A study of Mus musculus with 10 samples.

How the data were processed

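RNA was measured in the tibialis anterior, a fast-twitch muscle of the lower hind limb, of C57BL/6 mice aged 6 months and fasted for 3 h. The labels give 10 libraries, 5 from mice labelled Lrtm1 knockout and 5 from floxed controls, and the series' design text gives a smaller group size than the labels do; all 10 libraries were used as labelled. The labels also give a litter for each library. Litter 108 holds 2 knockout and 1 control libraries, litter 110 holds 1 and 2, and litter 112 holds 2 and 2. The labels do not say in words that each library came from a separate animal, so p-values measure the spread between these samples.

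RNA was extracted with TRIzol and made into stranded oligo-dT libraries with a BGI/MGI directional kit, per the labels' protocols. Reads were handled with fastp (read trimming), kallisto (assignment of reads to transcripts without full alignment) and limma, per the submitters' processing notes, which name no versions. The genome build, the transcript annotation and whether counting used the strand are not given in the sources used here. The authors deposited 1 table of adjusted log2 CPM (log2 of counts scaled to the library total), with an Ensembl identifier and, for most, a symbol for 13492 genes. Converted back to CPM, the deposited log2 values of a library sum to between 960166 and 1016398. Of the rows, 146 have no symbol and 20 share a symbol with another row. Read totals and counts per gene were not used here and cannot be worked back from adjusted log2 values, so the depth per library is unknown and no counting interval is given.

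What the authors' adjustment removed was checked on the deposited log2 values themselves. With genotype in the fit, the largest difference between litters in any gene was 6.4e-14, which is rounding error. Among the 126 splits of the libraries into 5 and 5, this held for 1, the labelled one, so litter was removed with genotype kept. Genotype and litter leave 6 residual degrees of freedom, but the residuals of all genes spanned only 3 dimensions, so 3 further terms had also been removed with genotype kept. What those terms were is not given in the sources used here. SDs printed here are those of the adjusted values and leave out the variation that was removed.

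Differences between groups were tested gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean expression), two-sided, with litter and genotype as terms. Genes with a mean log2 CPM of at least 0 were tested, which kept 12223 and left out 1269. The threshold was a Benjamini-Hochberg adjusted p of 0.05. This planned fit counts 6 residual degrees of freedom where 3 remain. A further fit, chosen after seeing the data, adds the 3 removed terms and so counts 3 residual degrees of freedom; its differences are identical and its adjusted p is printed beside the planned one, as the value "with the removed terms counted". Its standard errors are still lower bounds, because any overlap of the removed terms with genotype cannot be recovered. No pseudocount was added. For Lrtm1 a two-sided exact permutation test over the 252 assignments of 5 labels to 10 libraries was run on values centred by litter. The exact test gave p = 0.00794, the smallest that 5 against 5 allows, for Lrtm1 and for Cacna2d3 alike. Because the values were adjusted with the labelled split kept, the assignments are not exchangeable, and this test was not used for either gene.

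Before the data were examined, 33 gene lists were written, covering pathways, fibre types, cell states, complexes and cell types of muscle tissue. Lists with at least 3 measured members were tested, which was 31; the list for lymphocytes and neutrophils had too few, and sex-linked transcripts served only as a check of the samples. Lists were compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The named genes were chosen by a rule fixed at the same time. It takes Lrtm1 and Cacna2d3, then the 10 largest differences in each direction among genes past the threshold with a mean log2 CPM of at least 1 and a symbol other than a predicted model. From each list it takes up to 4 members past the threshold, or 2 that are closest where none passed, and it adds Myh1, Myh2, Myh4, Myh7, Slc2a4, Insr, Irs1 and Irs2 as references. Genes named outside that rule are said to be so. Positions, transcript lengths and GC content came from GENCODE release M21 on GRCm38, matched by Ensembl identifier for 99.1% of the tested genes. Length and GC content are those of each gene's longest annotated transcript, which need not be the one expressed. The deposited table holds no positions.

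The steps were tested on simulated data for the comparison of libraries labelled knockout with libraries labelled control, on 12223 genes of which 200 were changed. Simulated genes varied independently of each other. Their spread was taken from the residuals of the deposited values, so it leaves out the variation that the authors' terms removed. Recovery from values never adjusted could therefore be lower than given here. On unadjusted simulated values the planned fit recovered 71% of genes changed by a log2 difference of 0.5 and 90% of those changed by 1, with 7 false calls among 168. After an adjustment like the authors', the planned fit made 509 false calls among 697, while the fit with the removed terms counted made 3 among 136 and recovered 52% and 81%. In 20 simulated data sets with no change at all, adjusted in the same way, the planned fit called a median of 299.5 genes and at most 372, and the other fit a median of 0 and at most 1.

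The alternatives were fits without litter, with litter as a random effect and with the replicate number as a block; no filter and a stricter one (mean log2 CPM of at least 2); a further pseudocount of 1 CPM; quantile normalization and equal medians; eBayes without a trend and robust eBayes; array weights; an adjusted p of 0.1; and leaving out each library. Without control replicate 1, litter 108 holds no control, and without knockout replicate 3, litter 110 holds no knockout. With litter in the fit, that litter then no longer enters the comparison of genotypes. A term for sex was planned only if sex-linked transcripts split the samples. They did not: the Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 10 libraries. Ddx3y ran from 5.61 to 5.88 log2 CPM and Eif2s3y, the widest, from 4.75 to 5.32. The check was made on the adjusted values. Had sex been among the unnamed terms removed, these transcripts would be level in any case. The check therefore cannot show the sex of each library.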

Results

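Expression of 13492 genes was compared in tibialis anterior muscle between 5 libraries labelled Lrtm1 knockout and 5 labelled floxed control, from 3 litters that each held both genotypes. The series asks about Lrtm1, which encodes a leucine-rich repeat protein of the membrane, in insulin signalling and metabolism of muscle. Values are adjusted log2 CPM as the authors deposited them, and the depth behind them is unknown. The libraries were alike in overall distribution, with medians between 3.35 and 3.36 log2 CPM, and the 10 most abundant genes took between 31.2% and 32.7% of the CPM in each.

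Lrtm1 (ENSMUSG00000045776) was not lower in the libraries labelled knockout. It was 1.35-fold higher in them, at 6.12 ± 0.10 log2 CPM (SD, n = 5) against 5.68 ± 0.07 (SD, n = 5) in the libraries labelled control, or 69.7 ± 4.59 against 51.5 ± 2.47 CPM. Every library labelled knockout (5.97 to 6.21 log2 CPM) lay above every library labelled control (5.61 to 5.78). The log2 difference was 0.44 (SE 0.06), with an adjusted p of 0.00381. With the removed terms counted the SE was 0.07 and the adjusted p 0.0344. Within litters the log2 difference was 0.56 in litter 108, 0.41 in litter 110 and 0.38 in litter 112. All 1054 genes past the threshold in the planned fit likewise kept their direction in every litter, so this adds no support. The level of the targeted gene therefore does not bear out the genotype labels, and every direction below is drawn between libraries as labelled. Which part of Lrtm1 was deleted is not given in the sources used here, so a gene-level value may include reads from outside the deleted part and then checks nothing.

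Lrtm1 lies on chromosome 14, from 29018208 to 29033645 on the plus strand (GENCODE M21, GRCm38), and its 3 annotated transcripts have 3 exons each. The gene lies inside an intron of Cacna2d3 (ENSMUSG00000021991), a calcium channel subunit gene on the minus strand from 28904943 to 29721864, and no annotated Cacna2d3 exon overlaps it. Cacna2d3 was near the floor, at -0.94 ± 0.06 log2 CPM (SD, n = 5) in the libraries labelled knockout and -0.63 ± 0.09 (SD, n = 5) in the controls. Its mean was below the expression minimum. In the fit without that minimum its log2 difference of -0.31 did not pass the threshold (adjusted p = 0.142, and 0.775 with the removed terms counted).

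**Figure D1:**
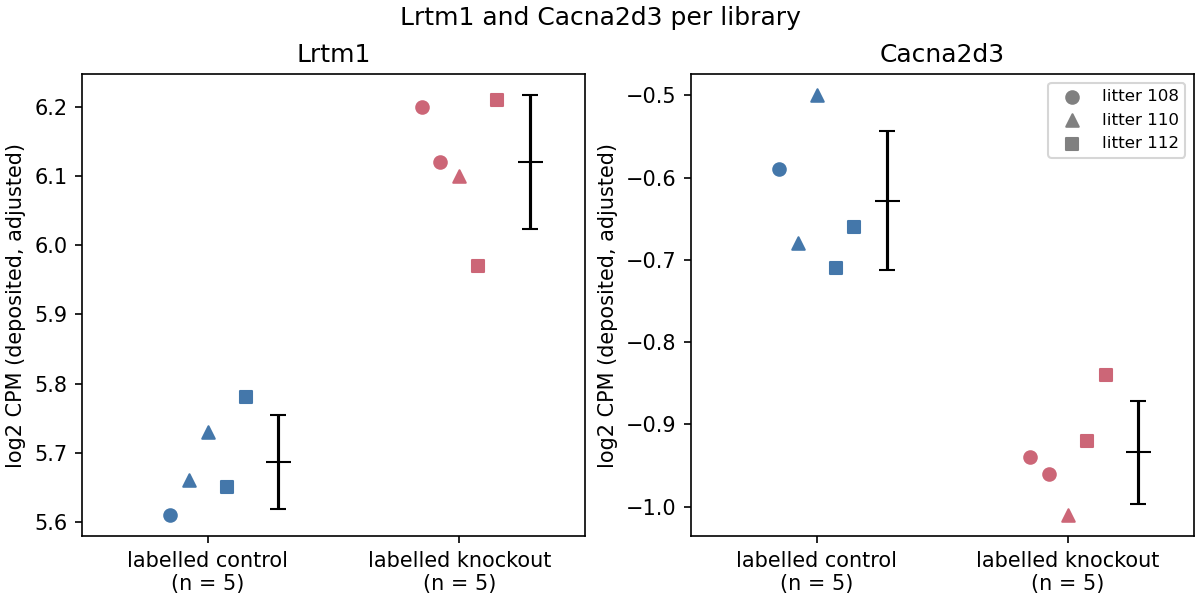
Deposited, adjusted log2 CPM of Lrtm1 (left) and Cacna2d3 (right) in each of the 10 libraries, grouped by label on the x axis; marker shapes give the litter, and the bars give the mean and SD of 5 libraries. All 5 libraries labelled knockout lie above all 5 labelled control for Lrtm1, at means of 6.12 and 5.68 log2 CPM.

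Among named genes with a mean log2 CPM of at least 1 that passed the threshold in both fits, 3 had the largest differences upward and 3 downward. Nr4a3, a nuclear receptor that is induced by exercise, was 5.38-fold higher in the libraries labelled knockout (log2 difference 2.43, SE 0.37). Igfn1, a sarcomeric protein of the Z-disc, was 2.58-fold higher (1.37, SE 0.09), and Irs2, the adaptor insulin receptor substrate 2, was 2.46-fold higher (1.30, SE 0.15). On the lower side, Erdr1 was 5.2-fold lower (-2.38, SE 0.29), the myosin-binding protein gene Mybph was 3.03-fold lower (-1.60, SE 0.22), and Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was 2.08-fold lower (-1.06, SE 0.15). In the planned fit the adjusted p was 0.0076 for Nr4a3, 0.000633 for Igfn1, 0.00243 for Irs2, 0.00323 for Erdr1, 0.00513 for Mybph and 0.00615 for Scd1. With the removed terms counted, the same order gave 0.0245, 0.000374, 0.00665, 0.0111, 0.0162 and 0.0245. In each of the 6 genes the 5 libraries labelled knockout all lay on the same side of the 5 controls. The groups did not overlap in 16.2% of all genes tested either, and the 6 were picked for their large differences. The lack of overlap therefore adds no support. Without control replicate 1, which also takes litter 108 out of the comparison, Nr4a3 and Scd1 fell short of the threshold, both at an adjusted p of 0.0511. Each gene held its direction in all 3 litters. So did all 1054 genes past the threshold in the planned fit and 47.9% of all genes tested, so that agreement adds no support. Nr4a3 ranged from 1.62 to 3.04 between litters, Irs2 from 1.05 to 1.46 and Erdr1 from -2.79 to -1.72.

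Of the other genes with large differences, the sperm channel subunit gene Catsper4 (log2 difference 0.95) and the phosphate transporter gene Slc20a1 (0.74) also rose in both fits, with adjusted p of 0.0345 and 0.0111 with the removed terms counted. Htra4 (0.96), BC002189 (0.76) and the copper transporter gene Atp7a (0.71) were higher in the planned fit, and Hp (-1.19), Adipoq (-0.98), Pck1 (-0.75), Arrdc2 (-0.62), Cfd (-0.62) and Col8a2 (-0.57) were lower, but none passed with the removed terms counted (adjusted p from 0.082 for Hp up to 0.332 for Col8a2). Hspa1a (0.96) and Hspa1b (0.92) are near-identical copies, and Rpl27-ps3 (-0.67) is a pseudogene, so reads could be split between copies and their values are uncertain.

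In all, 1054 of the 12223 genes tested passed the threshold in the planned fit, 629 higher and 425 lower in the libraries labelled knockout. Most differences were small, with a median absolute log2 difference of 0.231 among them; 8 were at least 2-fold higher and 8 at least 2-fold lower. The balance turned with transcript length, from 68 higher and 135 lower in the shortest of 5 length classes to 266 higher and 33 lower in the longest. With the removed terms counted, 41 genes passed, 33 higher and 8 lower, and all 41 were among the 1054. The groups did not overlap in 1979 genes (16.2%), where chance gives 0.794%, a comparison that the adjustment with genotype kept also moves. On simulated values with no change, the planned fit still called a median of 299.5 genes, so the larger count is not a count of changed genes. The number of genes past the threshold also changed when 1 library was left out. It was 101 without control replicate 1, 396 without control replicate 3 and 1709 without control replicate 5, and 454, 343, 162 and 480 without knockout replicates 1, 2, 3 and 5. Leaving out control replicate 1 or knockout replicate 3 takes all of litter 108 or 110 out of the comparison. The counts of 101 and 162 are therefore not the effect of 1 library alone. Of the 80 genes named by the rule that were past the threshold, Lrtm1 aside, 11 kept it with the removed terms counted, 14 without control replicate 1 and 22 without knockout replicate 3. Control replicate 5 stood apart from the other controls for Pck1, Pfkfb2, Hsp90aa1, Shmt2 and Irf7, control replicate 4 for Atp5g2 and Slc7a5, and knockout replicate 4 from its group for Rps6kb1.

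**Figure D2:**
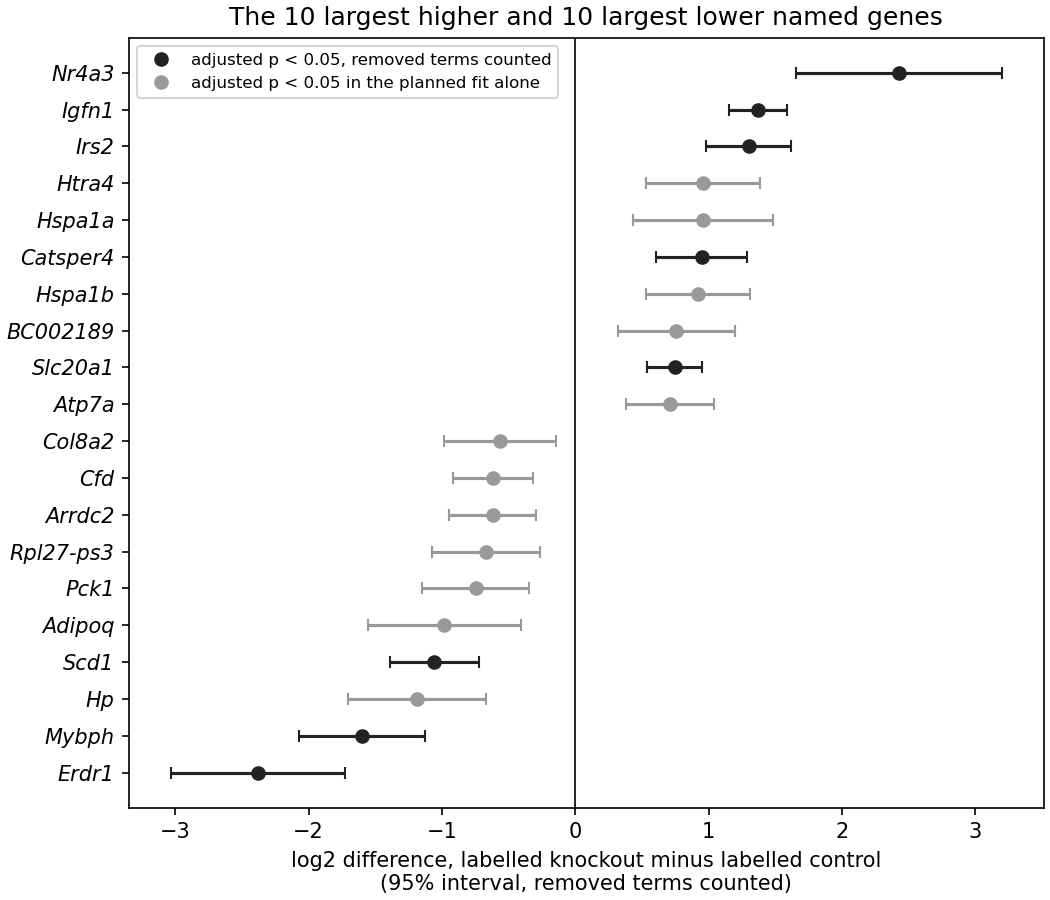
Log2 difference between libraries labelled knockout and control (x axis) for the 10 largest higher and 10 largest lower named genes (y axis); points are the fitted difference and bars the 95% interval with the removed terms counted. Black points passed the threshold in both fits and grey points in the planned fit alone; the values run from -2.38 for Erdr1 to 2.43 for Nr4a3.

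Both insulin receptor substrate genes were higher in the libraries labelled knockout, while the receptor and the insulin-responsive glucose transporter did not pass the test. Irs1 was 1.53-fold higher (log2 difference 0.62, SE 0.12; adjusted p = 0.0193, and 0.0839 with the removed terms counted), and Irs2 is given above. The Irs1 call was lost without control replicate 1 (adjusted p = 0.0715) or knockout replicate 3 (0.0899), each of which also takes its litter out of the comparison. Insr differed by 0.16 (adjusted p = 0.0652, and 0.0283 without control replicate 5) and Slc2a4, which encodes GLUT4, by 0.08 (adjusted p = 0.129). Of the 44 measured genes of insulin signalling, 3 were higher, 3 lower and 38 not past the threshold (7 higher and 5 lower adjusted over the list alone). Tsc1, a brake on mTOR complex 1, was among those higher (0.14), and Rps6kb1, which encodes the S6 kinase, among those lower (-0.16). The list as a whole did not pass (camera adjusted p = 0.155), and Irs2 alone of its genes passed with the removed terms counted.

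The list of genes induced by FoxO factors and in muscle atrophy was higher in camera (adjusted p = 0.00356), but did not pass with an estimated correlation (adjusted p = 0.411). Of 29 measured members 6 were higher and none lower (7 higher and 1 lower adjusted over the list alone), with a median log2 difference of 0.09. Fbxo32, the atrophy ubiquitin ligase atrogin-1, rose by 0.44 (SE 0.03, and 0.06 with the removed terms counted). Klhl38 rose by 0.46 (SE 0.06, and 0.07 with the removed terms counted), and Irs2 is itself a member. These 3 passed in both fits (Fbxo32 and Klhl38 adjusted p = 0.0129 and 0.0332 with the removed terms counted). Klf15 was higher by 0.23 in the planned fit (adjusted p = 0.0329, and 0.307 with the removed terms counted). Fry, which does not compare the list with other genes, gave an adjusted p of 0.0103.

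Genes of fuel use moved in both directions and none of these lists passed in camera. In glucose uptake and glycogen, 1 of 24 measured genes was higher, the hexokinase gene Hk2 (log2 difference 0.33), and 1 lower, Ppp1r3c (-0.17), which targets a phosphatase to glycogen; the counts were the same adjusted over the list alone (camera adjusted p = 0.391), although fry gave an adjusted p of 0.00107 in the planned fit. In glycolysis, Hk2 and Pfkfb2 (0.33) were the 2 higher of 25 and none were lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.556). In the pyruvate dehydrogenase and tricarboxylic acid cycle list, 1 of 31 was lower and none higher, both overall and adjusted over the list alone, namely the pyruvate dehydrogenase phosphatase gene Pdp1 (-0.22; camera adjusted p = 0.351). Of 39 genes of fatty acid uptake and oxidation, 3 were higher, Lpl (0.29), Ppard (0.22) and Ppara (0.67), and 3 lower, Fabp3 (-0.23) among them (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.351). Of 30 genes of lipid synthesis and storage, 3 were higher, including Lpin1 (0.19) and Mlxipl (0.22), and 2 lower, Scd1 and Dgat1 (-0.21), against 5 and 6 adjusted over the list alone (camera adjusted p = 0.932). In the lipid list the median (0.02) and mean (-0.02) had opposite signs. Of the genes in this paragraph, Scd1 alone passed with the removed terms counted. Adipocytes also express Scd1, and adipocyte markers were lower too, as given below.

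Lists of ribosomal proteins, nuclear-encoded respiratory chain subunits and proteasome subunits were slightly lower in camera in the libraries labelled knockout (adjusted p = 1.73e-08, 8.25e-06 and 0.000266). None of them passed with an estimated correlation (adjusted p = 0.672, 0.672 and 0.328). Of 76 ribosomal protein genes, 73 had a difference below 0, with a median log2 difference of -0.10; 6 were lower and none higher (12 and 0 adjusted over the list alone), among them Rpl32 (-0.18), Rpl23a (-0.18), Rpl26 (-0.21) and Rps10 (-0.20). Of 77 nuclear-encoded respiratory chain subunits, 70 lay below 0, with a median of -0.05; 7 were lower and none higher (8 and 0 adjusted over the list alone), including Cox5b (-0.13), Ndufb3 (-0.12), Atp5e (-0.22) and Atp5g2 (-0.41). Of 31 proteasome subunits, 26 lay below 0, with a median of -0.06; 4 were lower and none higher (5 and 0 adjusted over the list alone), namely Psmd14 (-0.16), Psma7 (-0.12), Psmc3 (-0.09) and Psma1 (-0.14). No single member passed with the removed terms counted, and ribosomal protein genes and Atp5g2 have processed pseudogenes with which reads could be shared. Fry gave an adjusted p of 0.00486 for the proteasome. Members of these lists have short transcripts, and across all genes the median log2 difference ran from -0.04 in the shortest of 5 length classes to 0.05 in the longest. The 13 transcripts of mitochondrial DNA showed no gene past the threshold, also when adjusted over the list alone (camera adjusted p = 0.859); mt-Co3 differed by -0.17 and mt-Nd4l by 0.13. Among 30 regulators of mitochondrial biogenesis, Vegfa (0.33) and Nr4a3 were higher, in both fits, and the mitophagy kinase gene Pink1 was lower (-0.15) in the planned fit (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.399).

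Of 25 immediate early genes, 4 were higher and none lower (5 and 0 adjusted over the list alone): Nr4a3, Maff (log2 difference 0.65), Nr4a2 (0.50) and Klf4 (0.35). The camera adjusted p was 0.0483, with an adjusted p of 0.672 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.232), control replicate 5 (0.115), knockout replicate 1 (0.0824) or knockout replicate 5 (0.127). It was also lost in 5 other settings (0.0594 to 0.145), among them array weights, which did not converge. Of 23 heat shock genes, 6 were higher, including Hsp90aa1 (0.38), Hsph1 (0.20) and the copies Hspa1a and Hspa1b, and 1 was lower, Hsf2 (-0.24), against 8 and 2 adjusted over the list alone. The camera adjusted p was 0.0296, with an adjusted p of 0.672 with an estimated correlation, and the call was lost without control replicates 1, 4 or 6 or knockout replicate 3 (adjusted p = 0.0647, 0.0534, 0.0937 and 0.155) and among genes with a mean log2 CPM of at least 2 (0.163). In the integrated and endoplasmic reticulum stress list, 3 of 28 were higher, Slc7a5 (0.42), Atf5 (0.12) and Shmt2 (0.13), and 1 lower, Ddit3 (-0.24), against 4 and 2 adjusted over the list alone (camera adjusted p = 0.901; median 0.01 and mean -0.02).

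The list of interferon-stimulated genes was lower in camera (adjusted p = 0.00257), but did not pass with an estimated correlation (adjusted p = 0.672). Of 25 measured, 22 lay below 0 with a median log2 difference of -0.17, and Irf7 (-0.50) and Ifit2 (-0.48) were lower, both overall and adjusted over the list alone, with none higher. The camera call was lost without control replicate 5 (adjusted p = 0.0647) and among genes with a mean log2 CPM of at least 2 (0.343). It was also lost with array weights (0.0531), a fit that did not converge. In the fibroblast growth factor and ERK list, 1 of 30 was higher, the cyclin gene Ccnd1 (0.37), and 2 lower, Fgfbp1 (-0.62) and Fgf7 (-0.29), against 2 and 3 adjusted over the list alone (camera adjusted p = 0.398). Among 19 circadian clock genes, Nfil3 (0.30) and Rora (0.15) were higher and Bhlhe41 (-0.19) lower, also when adjusted over the list alone (camera adjusted p = 0.841). None of the genes of this paragraph passed with the removed terms counted.

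None of 20 fast fibre contractile genes passed the threshold, also when adjusted over the list alone (camera adjusted p = 0.859). Among the myosin heavy chains, Myh4 was the most abundant at 15.07 ± 0.05 log2 CPM against 14.94 ± 0.12 (SD, n = 5 each) and differed by 0.13 (adjusted p = 0.324); Myh1 differed by 0.18, Myh2 by -0.17 and the slow-fibre Myh7 by 0.98, with a wide 95% interval from -0.24 to 2.19. Pfkm (0.09) and Pvalb (-0.11) came closest to the threshold among fast genes. Of 18 slow fibre genes, Atp2a2, the slow calcium pump, was higher (0.21) and Casq2, the cardiac and slow calsequestrin, lower (-0.39), against 1 and 2 adjusted over the list alone (camera adjusted p = 0.398). Both also belong to the 33 genes of excitation-contraction coupling, where Srl (0.14) was the other gene past the threshold, with the same counts of 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.932). Among 22 satellite cell and myogenic genes, Igf1 was higher (0.49) and none lower, and none passed adjusted over the list alone (camera adjusted p = 0.617; median -0.001 and mean 0.05). Among 21 genes of the neuromuscular junction and denervation, 18 lay above 0; Runx1 was higher (0.46), none were lower, and none passed adjusted over the list alone. That list gave a camera adjusted p of 0.113, and of 0.0447 with the removed terms counted, 0.0481 without control replicate 3 and 0.0477 without knockout replicate 5. Its adjusted p was 0.672 with an estimated correlation, and 0.69 so with the removed terms counted.

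Of the lists of other cell types, those of adipocyte and tendon markers passed in camera, both lower in the libraries labelled knockout, and neither passed with an estimated correlation. Among 10 adipocyte markers, 9 lay below 0 with a median log2 difference of -0.41; leptin, Lep (-2.21), Cidec (-1.20), Adipoq (-0.98) and complement factor D, Cfd (-0.62), were lower and none higher (6 and 0 adjusted over the list alone). The adipocyte list gave a camera adjusted p of 0.00156 and an adjusted p of 0.672 with an estimated correlation, and no member passed with the removed terms counted (Lep adjusted p = 0.0642). Lep and Cidec, the largest differences, were at low levels, with means over all libraries of 0.51 and 0.52 log2 CPM. Among genes with a mean log2 CPM of at least 2 the adipocyte list did not pass (0.0781). Scd1, Hp and Pck1, which adipocytes also express, were lower too. Scd1 and Hp differed most in litter 110 and least in litter 112, as Adipoq, Cfd and Cidec did, while Pck1 and Lep followed other orders. Whether they moved together with these markers was not tested. Among 12 tendon markers 11 lay below 0, Cilp2 (-0.55) and Chad (-0.53) farthest; none passed singly or adjusted over the list alone, though without control replicate 5 both Cilp2 (adjusted p = 0.0108) and Chad (0.0107) did. The tendon list gave a camera adjusted p of 0.0433, with an adjusted p of 0.709 with an estimated correlation, and lost its call without control replicates 1, 4 or 6 (0.0528, 0.139 and 0.163) or knockout replicates 3 or 4 (0.278 and 0.122), and in 5 other settings (0.0513 to 0.145).

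The remaining cell type lists did not pass in camera. Of 28 fibroblast and matrix genes, Thbs1 (log2 difference 0.60) and Col15a1 (0.18) were higher, also when adjusted over the list alone, and none lower, although 22 lay below 0 and the list's direction was downward (camera adjusted p = 0.071). None of 15 macrophage genes passed (camera adjusted p = 0.155; Lgmn -0.18, Cd163 -0.24) and none of 8 Schwann cell and nerve genes (0.249; Ngfr -0.21, Scn7a -0.29), also when each was adjusted over the list alone. Leaving out single libraries changed these outcomes. The fibroblast list passed without control replicate 5 (0.00139) or knockout replicates 4 (0.039) or 5 (0.0242), the macrophage list without control replicate 5 (0.028) and the Schwann cell list without knockout replicate 4 (0.0039). With array weights the values were 0.00339, 0.0316 and 0.027, but that fit did not converge and decides nothing. With all libraries these lists had an adjusted p of 0.709, 0.672 and 0.748 with an estimated correlation. Lgmn passed without control replicate 4 (0.022) and Cd163 without control replicate 5 (0.037). The endothelial gene Eng was higher (0.31) among 18, also when adjusted over the list alone (camera adjusted p = 0.351). Of 13 smooth muscle and pericyte genes, Smtn was lower (-0.14), against 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.932). None of 7 erythrocyte genes passed, against 1 lower adjusted over the list alone (camera adjusted p = 0.344); Hba-a2, which has a near-identical copy, differed by -0.18 (adjusted p = 0.0193 without control replicate 4) and Bpgm by -0.09 (0.0202 without control replicate 5). Across the 31 lists, 9 passed in camera, 3 higher and 6 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.328 and the unadjusted p of the proteasome (0.0106) and of FoxO and atrophy targets (0.0265) lay under 0.05. In fry 3 passed (proteasome, FoxO and atrophy, glucose uptake and glycogen), and with the removed terms counted its smallest adjusted p was 0.187.

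**Figure D3:**
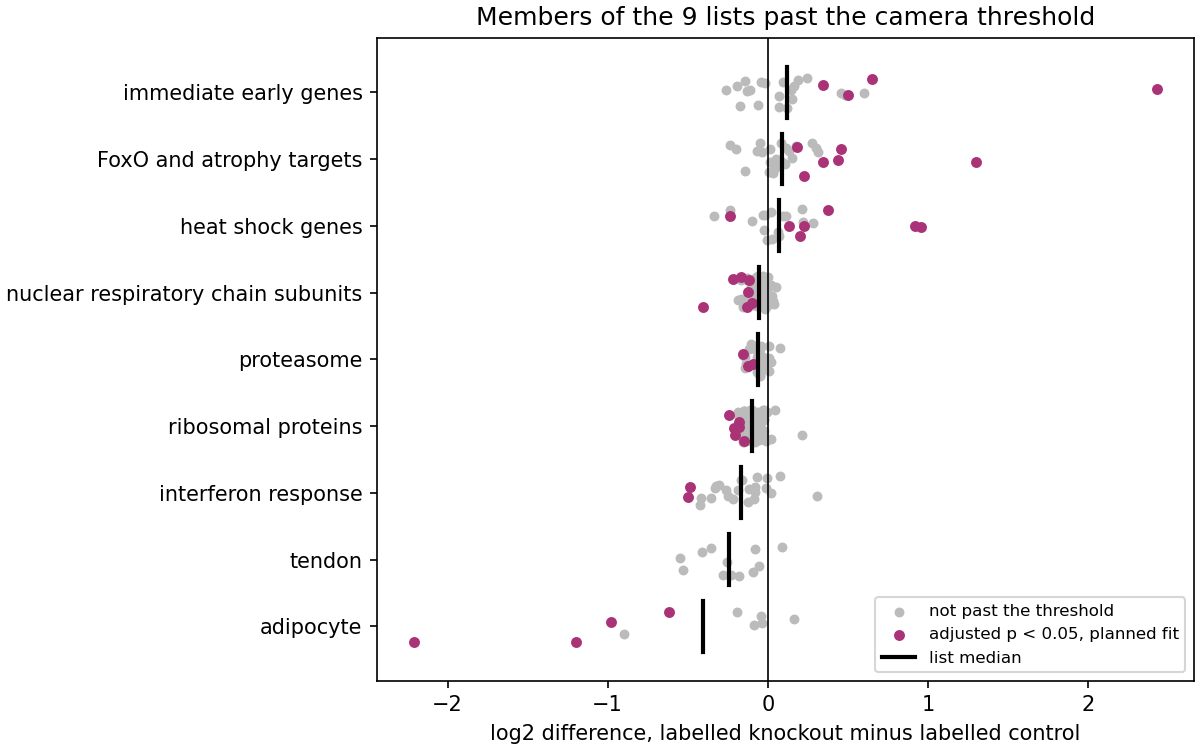
Log2 difference between libraries labelled knockout and control (x axis) for each measured member of the 9 lists past the camera threshold (y axis); purple points are genes past the threshold in the planned fit, grey points are not, and black bars are list medians. Medians run from -0.41 for adipocyte markers to 0.12 for immediate early genes, and those of ribosomal proteins, respiratory chain and proteasome lie within 0.10 of 0.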

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

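In this part, the tests of the transcript level of Lrtm1, its overlapping gene and its neighbourhood were chosen after the results were seen. So were those of the residual degrees of freedom and of the correlation within lists. Those on simulated values without effect, on other splits of the libraries and on matched random lists were set out before their own outcomes were seen. The simulated test was set out after the count of 41 genes was known, and the matched lists were drawn for lists already seen to be lower.

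A single library stood apart from the other 4 of its group for 9 of 260 combinations of a named gene, those named after seeing the data included, and a group, where chance gives about 1 in 20, or 13. The gap to the nearest library as a share of the group's range was 0.814 for Pck1, 0.737 for Pfkfb2, 0.766 for Hsp90aa1, 0.797 for Shmt2, 0.752 for Irf7 and 0.766 for Nnat, all in control replicate 5. It was 0.722 for Atp5g2 and 0.711 for Slc7a5 in control replicate 4, and 0.796 for Rps6kb1 in knockout replicate 4. For Pck1 the level was 1.13 log2 CPM against 1.57 to 1.67 in the other controls, and for Nnat 1.15 against 1.88 to 2.10. Control replicate 5 lay toward the libraries labelled knockout for Pck1, Pfkfb2, Hsp90aa1, Shmt2 and Nnat, and away from them for Irf7. Without control replicate 5 the number of genes past the threshold was 1709.

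The first pattern is the number of genes past the threshold, 1054. With the removed terms counted the number was 41; how many of the other calls were false is not known, since simulated values with no effect gave the planned fit a median of 299.5 calls and at most 372, and the stricter fit also missed simulated changes (52% and 81% recovered, against 91% and 97%). In 20 such data sets the stricter fit made a median of 0 calls and at most 1, below 41. The simulated terms were removed from residuals alone and so could not overlap with genotype, as the authors' terms may have done. Simulated genes also varied independently, while real genes shared variation (estimated correlation 0.308 for ribosomal proteins). Shared variation can widen the spread of such counts, so this comparison cannot decide. Among 100 splits of the 10 libraries, drawn with the labelled one included, 1 gave as many calls, the labelled split itself, and the highest of the others gave 98; because the values were adjusted with the labelled split kept, this count cannot say whether chance is excluded. Beside a genotype effect behind the 41 genes, chance therefore stays open, and so does a part left by removed terms that overlapped with genotype. The deposited values cannot show that part.

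The second pattern is Lrtm1 being higher in the libraries labelled knockout. The mean of Lrtm1 in them, 6.12 log2 CPM, argues against absence of the transcript, as far as adjusted gene-level values can show. Cacna2d3 reached at most 0.709 CPM in any library, far below the Lrtm1 difference of 18.3 CPM. Unspliced Cacna2d3 reads over Lrtm1 would not enter that value, and whether counting used the strand is not known. Such reads are therefore not excluded. Within 5 Mb of Lrtm1, 6 of 65 genes passed the threshold (9.23%, against 8.61% elsewhere; Fisher's exact test, two-sided, p = 0.823), which leaves a change of the neighbourhood open. Labels exchanged between the groups and a deletion that leaves most of the transcript in place cannot be told apart, because the libraries labelled control still held 5.68 log2 CPM and the deleted part is not known here. A regulatory response to the deletion, the biological explanation the design gives, was not tested. A part left by removed terms that overlapped with genotype also stays open for the difference in Lrtm1.

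The third pattern is the lower level of ribosomal proteins, respiratory chain subunits and proteasome subunits, all lists of short transcripts. Across genes, which are not independent replicates, the log2 difference rose with transcript length (Spearman's rho 0.232), from a median of -0.04 in the shortest of 5 length classes to 0.05 in the longest. Among 10000 random lists matched on length, GC content and expression, the median of the ribosomal proteins lay at percentile 0. That of the respiratory chain lay at 1.89 and that of the proteasome at 2.04. Lengths are those of each gene's longest annotated transcript, which need not be the one expressed. The match may thus be inexact, so the test cannot tell whether the trend with length and GC content is the whole cause. The matched lists also had medians below 0, of -0.05, -0.04 and -0.03, so the trend may account for part. Random lists do not share variation as members of a complex do: with an estimated correlation camera gave p = 0.145 for ribosomal proteins and 0.232 for the respiratory chain, as variation shared by members between libraries would give, and 0.0106 for the proteasome, which decides neither way (adjusted p = 0.328). Lower expression of these complexes linked to genotype stays open beside shared variation and the trend with length.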

How the results depend on the processing

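The alternative that counts the removed terms was chosen after seeing the data; the others were fixed before. Lrtm1 stayed higher and past the threshold in all of its alternatives (log2 difference 0.39 to 0.487, highest adjusted p 0.0344). Against 1054 genes past the threshold in the planned fit, 2608 passed without litter and 3275 with litter as a random effect (correlation -0.323), since both count degrees of freedom that the adjustment had used; 1914 passed at an adjusted p of 0.1 and 41 with the removed terms counted. Array weights gave 9924 but did not converge, with a weight of 124 for control replicate 3 and of 0.093 for control replicate 5. The replicate block gave 128, of which 127 were among the 1054. The labels do not say that a replicate number marks a litter: numbers 1, 3 and 5 share a litter between the groups and number 4 does not. Same-numbered libraries correlated at -0.846, 0.452, 0.032 and -0.502, none best with its own number, but the removal of litter pushes such correlations down within a litter, so they cannot show whether the numbers pair the samples. Leaving out 1 library gave 101 to 1709 genes: 101 without control replicate 1, 396 without control replicate 3, 1709 without control replicate 5, and 454, 343, 162 and 480 without knockout replicates 1, 2, 3 and 5; without the others the number stayed within 1.5 times. Without control replicate 1, litter 108 holds no control, and without knockout replicate 3, litter 110 holds no knockout. Under the litter term the counts of 101 and 162 therefore rest on the other litters and do not isolate a single library. Fewer libraries also leave fewer degrees of freedom. Beyond these and the adjustment, the cause was not tested.

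Of the gene lists, 9 in the planned fit became 4 with a mean log2 CPM of at least 2, where fewer genes were tested, 0 with an estimated correlation and 3 in fry, and the other alternatives stayed within 1.5 times (10 with the removed terms counted, 9 with the replicate block, where neuromuscular junction genes passed at 0.0279, and 6 to 10 without 1 library). Ribosomal proteins, respiratory chain, proteasome and FoxO targets passed camera in all 20 alternatives with the preset correlation, adipocyte markers in 19, interferon in 17, heat shock in 15, immediate early genes in 11 and tendon in 10. Array weights, whose fit did not converge, count among the 20. Of 128 named genes no direction reversed. Several alternatives, such as those of eBayes, of the filter and of the removed terms, leave the fitted differences as they are and could not reverse one. The 128 genes include 30 added after seeing the data, most of them for passing with the removed terms counted. Of the 80 past the threshold that the rule names, 11 kept it with the removed terms counted, 23 with the replicate block and 14 to 76 without 1 library. Lists were not run with litter as a random effect, which camera does not take, nor with robust eBayes, which does not enter camera. A term for sex was not run, as Y-linked transcripts did not split the adjusted values. Depth is unknown, so its limits cannot be given.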

Other observations

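The test of the contraction list below was set out before the values of its genes were looked up, though after the genes that prompted it had been seen. Ppargc1a, its largest difference, also belongs to the list of mitochondrial biogenesis regulators, so its value entered the test of that list as well. The genes in the next paragraph were chosen after their values were seen.

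Among the 41 genes past the threshold with the removed terms counted, several fall outside the gene lists. In the libraries labelled knockout, Flcn, which encodes folliculin, a regulator of mTOR complex 1, rose by 0.54 on the log2 scale (adjusted p = 0.00665 with the removed terms counted, as for all values here). The receptor gene Gpr157 rose by 0.62 (0.00665), Hipk2, a nuclear kinase, by 0.64 (0.0245), and Odc1, the rate-limiting enzyme of polyamine synthesis, by 0.53 (0.0245). Smad3, a mediator of TGF-beta and myostatin signals, rose by 0.35 (0.0418), Nos1, the neuronal nitric oxide synthase of the sarcolemma, by 0.35 (0.0489), Eya1, a cofactor in the fast fibre programme, by 0.34 (0.0495), the collagen chaperone gene Serpinh1 by 0.38 (0.0438) and Mettl21c, a muscle lysine methyltransferase gene, by 0.53 (0.0419). On the lower side, the imprinted gene Nnat fell by 1.77 (0.0162), with control replicate 5 apart from the other controls, the alcohol dehydrogenase gene Adh1 by 0.48 (0.0245) and the lens crystallin gene Crybb1 by 1.17 (0.0344), the last at a low level of 0.91 log2 CPM in the controls.

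Nr4a3, Irs2 and Vegfa rose in both fits. Of 23 heat shock genes 6 were higher and 1, Hsf2, lower in the planned fit, none passed with the removed terms counted, and the list gave an adjusted p = 0.672 with an estimated correlation. Whether these genes moved together was not tested, and in litter 112 Nr4a3 differed most (3.04) while Hspa1b (0.50) and Hsp90aa1 (0.27) differed least. A candidate explanation is a response of genes induced by contraction or cyclic AMP. A list of 11 further genes of that response, of which 10 were measured, had a median log2 difference of 0.21. Camera gave p = 0.0158 with the preset correlation and p = 0.121 with an estimated one, for 1 list, so the test leaves the hypothesis open. Ppargc1a, the coactivator of mitochondrial biogenesis, was 1.76-fold higher without passing (0.81, SE 0.22; adjusted p = 0.0523, 0.212 with the removed terms counted and 0.0182 without control replicate 5). The cyclic AMP phosphodiesterase gene Pde4d passed in the planned fit (0.23; adjusted p = 0.00615, 0.165 with the removed terms counted and 0.0511 without control replicate 1), and the values of Slc25a25 (0.32), Pde4b (0.24) and Hes1 (-0.34) did not pass. Slc25a25 passed without control replicate 6 (0.0489) or knockout replicate 4 (0.0158), and Hes1 without control replicate 4 (0.0323).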
